A study of Homo sapiens with 24 samples.

How the data were processed

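The series holds 24 single-colour bead arrays of total RNA from human umbilical vein endothelial cells, up to passage 6 and with an RNA integrity number above 7, per the labels' protocols. Per the labels, serum was withdrawn for 4 h or longer, diluent or 100 µM propranolol was given for 45 min, and 24 h at 2% oxygen or in normoxia followed. Each of the 4 groups (normoxia, 2% oxygen, normoxia with propranolol, 2% oxygen with propranolol) had 6 arrays. A description code and the BeadChip that carried each array, both from the labels, divide the arrays into 6 sets of 4 with 1 array per group. Sets 1 and 2 lay on BeadChips 1 and 2, sets 3 and 4 on BeadChip 3, and sets 5 and 6 on BeadChip 4. Set 1 had its untreated 2% oxygen array on BeadChip 2 and its other arrays on BeadChip 1, and set 2 the reverse. Differences that involve this array therefore cross BeadChips in sets 1 and 2, and a block by set does not remove that. Sets 1 and 5 carry the same code. The labels do not state what the code stands for or whether sets are separate donors or cultures, so all p-values measure the spread between these samples. For 2 arrays the labels say that the raw scanner file was not provided.

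The deposited signal table gives, per the file headers, a mean bead intensity for each probe and array on a linear scale that was not normalized between arrays, and whether a local background was subtracted is not stated. It also gives a detection p-value beside each intensity, per the file headers. From its values, the detection p moves in steps of 770 negative control probes. A second table deposited by the authors holds 1 log2 value per probe and array with the same median, 4.86, in every column, as quantile normalization leaves them. The submitters' processing notes name limma without a version or settings, and the background correction behind the log2 values is not stated. The signal table held 48210 lines, of which 103 repeated others with 0 differing values, 790 control probes and 47317 probes that were also in the log2 table. After centring each probe, every array correlated best with its own log2 column (lowest 0.735, highest with another column 0.418). Of the probes, 30110 carried 1 gene symbol, 8 carried several and 17199 carried none. The Entrez identifiers of 30071 matched the reference gene table (GRCh38.p14), which was used for names alone. 144 probes were left out of every table: those for Y-linked genes and XIST, which can identify a person.

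The intensities were background corrected by normexp with the detection p, given an offset of 16, quantile normalized and put on the log2 scale with limma's neqc (limma 3.58.1, statmod 1.5.0, R 4.3.3). Probes detected at a detection p under 0.05 on at least 6 arrays were kept, and each gene was represented by its brightest probe, which left 11914 genes of 19948 with a probe. 127 of these have a retired or placeholder symbol and could not be named. Median signal per array was 93.9 to 120.6, and 18628 to 20738 probes were detected per array. For arrays, the number of arrays limits the precision.

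All 24 arrays entered 1 limma linear model with a mean per group and moderated variances. The 5 contrasts were 2% oxygen against normoxia without the drug, propranolol against diluent at 2% oxygen, propranolol against diluent in normoxia, 2% oxygen against normoxia with the drug, and the difference between the oxygen responses (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. No label states that arrays are paired, so the model had no block. The deviations of arrays from their group means were then checked. Arrays of 1 set in different groups correlated at 0.19 to 0.79 (36 pairs, median 0.58), and arrays of different sets and groups at a median of -0.12. Arrays in different groups of sets 1 and 5, which share a code, correlated at 0.05 to 0.30 (median 0.22). Of the arrays, 24 of 24 correlated best with an array of their own set. The sets therefore pair the arrays, and a model with set as a replicate block is given beside a result where it changes the call or moves a count by over 1.5 times. That block lowered the mean residual SD from 0.296 to 0.201 on the log2 scale.

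32 gene lists with 675 genes, 633 of them with a probe, were fixed before the data were examined, as were the model, the contrasts, the alternatives and the genes to be named, except for the 4 additions stated with the results. The lists cover HIF target genes, glycolytic enzymes, angiogenic factors and receptors, cholesterol synthesis and uptake, fatty acid synthesis, lysosomal genes, autophagy genes, ATF4 and integrated stress response genes, endoplasmic reticulum chaperones and the unfolded protein response, heat shock proteins (cytosolic ones with the mitochondrial HSPD1 and HSPE1), NRF2 targets, metallothioneins, p53 targets, apoptosis regulators, DNA replication genes, mitotic genes, respiratory chain subunits, cytosolic ribosomal proteins, collagens and collagen-modifying enzymes, TGF-beta and endothelial-to-mesenchymal transition genes, NF-kB inflammatory and adhesion genes, interferon-stimulated genes, endothelial identity genes, KLF2 and KLF4 flow-responsive genes, beta-adrenergic receptor and cAMP-CREB genes, immediate early genes, and markers of smooth muscle, fibroblasts, leukocytes, erythroid cells, lymphatic endothelium and epithelium or amnion. The 30 lists with at least 5 tested genes were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and contrasts, and again with the correlation estimated from the data. Erythroid markers had 1 tested gene and lymphatic markers 3, so those lists were not tested. For each list the mean change in each set was also taken, with an exact two-sided sign-flip permutation test over the 6 sets, whose smallest possible p is 0.0312. Every sign-flip p treats the 6 sets as independent. Sets 1 and 5 share a code and their arrays correlated, so these p-values may be too small.

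Named genes are, per contrast, the 8 largest increases and 8 largest decreases among called genes with the same sign in 6 of 6 sets, up to 2 members with the smallest adjusted p of each list that camera called, and preset genes, among them VEGFA, ADM, CA9, SLC2A1, PDK1, BNIP3, EGLN3, ANGPTL4, HIF1A, EPAS1, ADRB1, HMGCS1, DDIT3 and ANGPT2. Y-linked genes, XIST, placeholder symbols and probes without a single symbol were skipped, and where fewer genes passed, all that passed were taken. CA9 and ADRB1 were not among the genes tested, because no probe for them passed the filters. Small RNAs described under the closing observations were singled out after their values were seen.

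The share of the oxygen response retained with propranolol was measured per set on genes called in the other sets, as the ratio of the mean signed oxygen change with the drug to that without it. Genes that propranolol moved against the oxygen response were counted beside simulated unchanged groups, independent lists and splits of the shared arrays, since both contrasts use the 2% oxygen arrays with opposite signs.

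The pipeline was tested on simulated data with 200 changed genes of 11914 in 5 runs. For the oxygen contrast it recovered 52.5%, 89.0% and 97.6% of genes changed 1.5-, 2- and 3-fold without the block, with 5.21% false calls among the calls. For the interaction it recovered 22.7%, 67.2% and 88.5% of genes whose drug effect differed 1.5-, 2- and 3-fold between oxygen levels, and 49.9%, 91.0% and 98.8% with the set block. A simulated retained share of 0.5 was measured as 0.505. All simulations without the block, this one included, drew arrays independently and so lacked the pairing by set of the real arrays. Their rates need not hold for the real arrays. Those with the block added differences between sets, so the percentages with and without it come from different simulated data.

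The alternatives changed the background correction, normalization, detection filter, probe choice, array weights, variance prior, fold threshold, arrays in the model, blocks, list test and correlation, used the authors' log2 values, or left out each array, each set, or the 2 arrays without a scanner file. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.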

Results

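RNA levels were measured on 24 bead arrays in human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein. The cells were kept in normoxia or at 2% oxygen for 24 h, each with diluent or with 100 µM propranolol, an antagonist of beta-adrenergic receptors, and each of the 4 groups had 6 arrays. Detected probes numbered 18628 to 20738 per array and median signals 93.9 to 120.6, and 11914 genes were tested. Changes are given as fold or as log2 differences of group means ± SE (n = 6 arrays per group), with adjusted p-values from limma over all genes tested. Genes named as changed moved the same way in 6 of 6 sets of arrays unless another count is given. Block counts come from the model in which the 6 sets form a replicate block.

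The first comparison asked which genes 2% oxygen changed in cells without the drug. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 12.7-fold (3.66 ± 0.51, adjusted p = 7.48e-05), and its other 2 probes rose by 1.73 and 2.30. SLC2A1, the glucose transporter GLUT1, rose 4.67-fold (2.22 ± 0.18, adjusted p = 6.1e-08), and ANKRD37, an ankyrin repeat protein, rose 6.80-fold (2.77 ± 0.30). ADM, the vasodilator peptide adrenomedullin, rose 2.32-fold (1.21 ± 0.16, adjusted p = 3.38e-05), and VEGFA, the main endothelial growth factor, rose 1.80-fold (0.85 ± 0.19, adjusted p = 0.00831; detected on 4 of 6 normoxia arrays). Of the 41 HIF target genes tested, 16 rose and 0 fell (22 rose and 1 fell adjusted over the list alone, and 25 rose under the block). The list's mean change was 0.67 ± 0.07 (SD over 6 sets; camera adjusted p = 6.32e-21, and adjusted p = 3.21e-06 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, was not detected in normoxia and rose at least 1.94-fold, and P4HA1, a collagen prolyl hydroxylase, rose by 0.93 ± 0.09. Other HIF targets did not pass the test: the mitophagy receptor BNIP3 had 0.21 (adjusted p = 0.501) and the pyruvate dehydrogenase kinase PDK1 0.06 (adjusted p = 0.914). PDK1 was detected on only 2 of 6 normoxia and 3 of 6 hypoxia arrays, so this value says little about its response. HIF1A mRNA itself had -0.41 ± 0.13 (adjusted p = 0.0864), which passed under the block (adjusted p = 0.000621). EPAS1, which encodes HIF-2 alpha, had -0.23 and ANGPT2 -0.19.

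Glycolytic enzymes rose as a list, with 8 of 18 tested members higher and 0 lower (10 adjusted over the list alone; mean 0.49, camera adjusted p = 1.26e-09, and 0.0226 with an estimated correlation). ENO2, an enolase, rose by 0.92 ± 0.15. The glycolytic list also holds the transporters SLC2A1, SLC2A3 and SLC16A3. HK2, ENO2, SLC2A1 and SLC2A3 are on both this list and the HIF list, so the rises of these lists are not fully separate. Among genes outside these lists, AK4, a mitochondrial adenylate kinase, rose 4.81-fold and HSD17B2, a steroid dehydrogenase, rose by 1.99 ± 0.34 (detected on 4 of 6 normoxia arrays). SYTL2, a synaptotagmin-like protein of vesicle transport, rose 5.15-fold and ADSS1, an adenylosuccinate synthase, rose by 1.78 ± 0.17 on their brightest probes, but the other probe of each had -0.01 and 0.07. They were detected on only 2 and 3 of 6 normoxia arrays. The NF-kB inflammatory and leukocyte adhesion genes rose in 5 of 22 (12 adjusted over the list alone and 13 under the block; mean 0.57 ± 0.16, camera adjusted p = 1e-08, and 0.0235 with an estimated correlation). Among them ICAM1, an adhesion molecule for leukocytes, rose by 0.85 ± 0.15 and TNFAIP3, an inhibitor of NF-kB signalling, by 0.85 ± 0.14. Immediate early genes were higher in 5 of 15, including the phosphatase gene DUSP1 (0.87 ± 0.15) and MYC (0.63 ± 0.12; camera adjusted p = 0.00294, adjusted p = 0.0695 with an estimated correlation). Angiogenic factors and receptors were higher in 2 of 28 (7 higher and 1 lower under the block; camera adjusted p = 0.0231, adjusted p = 0.0926 with an estimated correlation). VEGFA, FLT1 and CXCR4 of the angiogenic list are also on the HIF list, as are P4HA1, P4HA2, PLOD2, LOX and LOXL2 of the collagen list. Collagens and their modifying enzymes were higher in 2 and lower in 1 of 26 (5 and 1 adjusted over the list alone, 13 and 1 under the block). Their mean was 0.32 (camera adjusted p = 0.000582; adjusted p = 0.312 with an estimated correlation, and 0.00226 with both it and the block). TGF-beta and endothelial-to-mesenchymal genes had a mean of 0.44 with 0 of 19 past the test (3 higher over the list alone; 9 higher and 1 lower under the block). For that list the camera adjusted p was 0.00293, and the adjusted p was 0.348 with an estimated correlation and 0.0258 with both it and the block.

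Cell division genes fell with 2% oxygen. Mitotic genes were lower in 27 of 28 (28 adjusted over the list alone; mean -1.47 ± 0.31, camera adjusted p = 9.56e-42, and 0.0226 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell 3.13-fold (-1.65 ± 0.21), CDC20, an activator of the anaphase-promoting complex, 3.57-fold, and BIRC5, the mitotic regulator survivin, 3.77-fold. DNA replication genes were lower in 20 of 23 (21 adjusted over the list alone; mean -1.15 ± 0.29, camera adjusted p = 1.49e-31, and 0.0108 with an estimated correlation). CDC45, a subunit of the replicative helicase, had -2.06 ± 0.32 and RRM2, a ribonucleotide reductase subunit, -1.14 ± 0.14 (detected on only 1 of 6 arrays at 2% oxygen). The 33 respiratory chain subunits had a mean of -0.13 with 0 past the test and 4 lower under the block (camera adjusted p = 0.000242; adjusted p = 0.0235 with an estimated correlation, and 0.105 with both it and the block). Cholesterol synthesis genes were lower in 3 of 20 (10 adjusted over the list alone, 11 under the block; mean -0.42 ± 0.15, camera adjusted p = 2.38e-07). Their adjusted p was 0.173 with an estimated correlation. ACAT2, an acetoacetyl-CoA thiolase, fell by 0.97 and EBP, a sterol isomerase, by 0.82. HMGCS1, the HMG-CoA synthase, had -0.83 ± 0.22 (adjusted p = 0.0266), a call that ended when replicate 1, 2 or 6 of the 2% oxygen group or replicate 4 or 5 of the normoxia group was left out. Fatty acid synthesis genes were lower in 1 of 13, the elongase ELOVL6 (-1.16 ± 0.19), and in 7 under the block and over the list alone (camera adjusted p = 0.000118, adjusted p = 0.166 with an estimated correlation). NRF2 targets were lower in 2 of 15 (3 over the list alone, 6 under the block; camera adjusted p = 0.000209, adjusted p = 0.173 with an estimated correlation). These were the quinone reductase NQO1 (2.37-fold, -1.24 ± 0.15) and the heme oxygenase HMOX1 (2.30-fold, -1.20 ± 0.21). Heat shock proteins were lower in 3 of 14 (6 under the block; camera adjusted p = 0.00319, adjusted p = 0.324 with an estimated correlation). These were the mitochondrial chaperonins HSPE1 (-0.56 ± 0.14, adjusted p = 0.0163) and HSPD1 (-0.38 ± 0.09, adjusted p = 0.0123) and the cytosolic HSP90AA1. The calls of HSPD1 and HSPE1 ended without the 2 arrays that have no scanner file, and with only the 2 compared groups in the model. Camera also called endoplasmic reticulum chaperones (adjusted p = 0.0525, and 0.0251 under the block) and metallothioneins (0.12, and 0.00231 under the block) under the block alone, both as higher. With both the block and an estimated correlation their adjusted p was 0.241 and 0.0537.

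In all, 552 genes passed the test with 2% oxygen, 190 higher and 362 lower, and 367 of them by at least 1.5-fold. Under the block 2010 passed (975 higher, 1035 lower), including the same 552. With median scaling in place of quantile normalization 266 were higher and 325 lower. With 2 arrays per group, the arrays of BeadChips 1 and 2, of BeadChip 3 and of BeadChip 4 alone gave 0, 1 and 0 calls. Genes called without those arrays had the same sign on them in 98.9%, 99.5% and 99.7%.

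**Figure D1:**
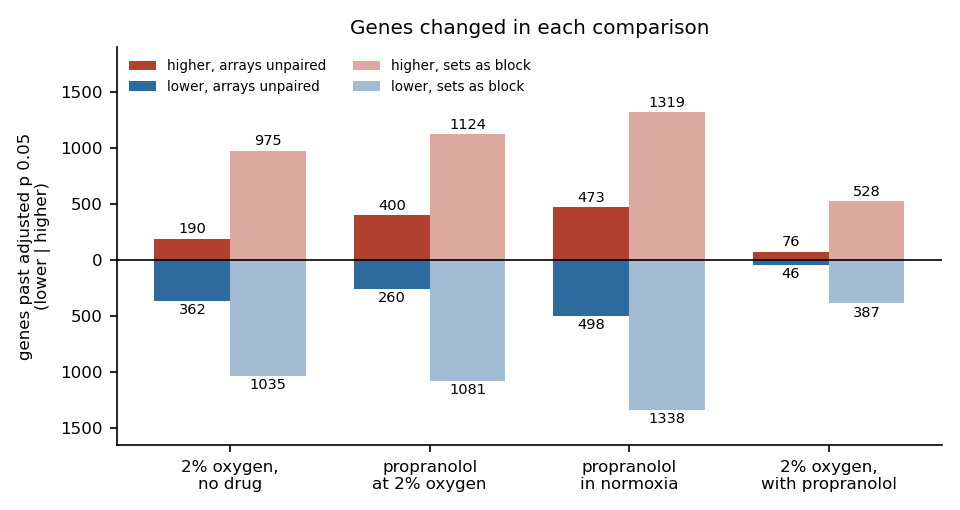
Number of genes past an adjusted p of 0.05 in each comparison (6 arrays per group; upward bars higher, downward bars lower, vertical axis in genes), from the limma model without a block (dark) and with the 6 sets as a replicate block (pale). Among the 4 comparisons other than the interaction, which had 0 genes, propranolol in normoxia changed the most (473 higher, 498 lower) and 2% oxygen in the presence of propranolol the fewest (76 higher, 46 lower).

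The second comparison, propranolol against diluent at 2% oxygen, asked what the drug did to hypoxic cells. PSAT1 rose 8.36-fold (3.06 ± 0.29, adjusted p = 4.12e-07) and PHGDH 6.11-fold (2.61 ± 0.34), both enzymes of serine synthesis. ASNS, the asparagine synthetase, rose 7.89-fold (2.98 ± 0.28), and SLC7A5, a transporter of large neutral amino acids, 5.01-fold (2.32 ± 0.23). The ATF4 and integrated stress response genes rose in 24 of 30, with 0 lower (29 adjusted over the list alone; mean 1.25 ± 0.33, camera adjusted p = 5.15e-41, and 0.00241 with an estimated correlation). They included TRIB3, a pseudokinase (2.31 ± 0.22), and DDIT3, the transcription factor CHOP (1.13 ± 0.17). STC1, a secreted glycoprotein, rose by 2.11 ± 0.39, FABP3, a fatty acid binding protein, by 2.46 ± 0.37 (detected on 3 of 6 arrays without the drug), and MYCN, a transcription factor of the MYC family, by 2.59 ± 0.38 (0.54 on its other probe).

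Cholesterol synthesis genes rose in 15 of 20 with 0 lower (17 adjusted over the list alone; mean 0.86 ± 0.27, camera adjusted p = 6.94e-22, and 0.0209 with an estimated correlation). HMGCS1 rose 2.57-fold (1.36 ± 0.22, adjusted p = 0.000359), the lanosterol demethylase CYP51A1 by 1.13 ± 0.14 and INSIG1, the sterol-sensing regulator of SREBP processing, by 1.14 ± 0.16. Fatty acid synthesis genes rose in 10 of 13 (10 adjusted over the list alone; mean 0.70 ± 0.14, camera adjusted p = 1.34e-17, and 0.00746 with an estimated correlation). LPIN1, a phosphatidate phosphatase, had 1.17 ± 0.11 and ACSS2, an acetyl-CoA synthetase, 1.09 ± 0.13. NRF2 targets rose in 8 of 15 (10 adjusted over the list alone; mean 0.65 ± 0.16, camera adjusted p = 4.18e-13, and 0.0179 with an estimated correlation). HMOX1 was 3.89-fold and NQO1 2.03-fold higher. Lysosomal genes were higher in 3 of 30 (8 higher and 2 lower over the list alone, 11 and 2 under the block), led by the cholesterol transporter NPC1 (1.28 ± 0.14). Their camera adjusted p was 0.000301, and the adjusted p was 0.287 with an estimated correlation and 0.0442 with both it and the block. Autophagy genes were higher in 2 of 20, among them MAP1LC3B, which encodes LC3B (0.57 ± 0.11). Their camera adjusted p of 0.0473 became an adjusted p of 0.0941 with an estimated correlation and 0.0584 under the block. The KLF2 and KLF4 flow-responsive genes were higher in 3 and lower in 1 of 13, with KLF2 at 0.60 ± 0.13 (camera adjusted p = 0.0335, adjusted p = 0.287 with an estimated correlation).

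Genes for adhesion of leukocytes and for chemokines were among the largest decreases with propranolol at 2% oxygen. VCAM1, an adhesion molecule, fell 6.46-fold (-2.69 ± 0.58, adjusted p = 0.00485; detected on 4 of 6 arrays with the drug), CCL2, the monocyte chemokine MCP-1, 5.41-fold (-2.44 ± 0.39) and CXCL1, a neutrophil chemokine, 3.41-fold (-1.77 ± 0.36). SELE, E-selectin, fell 5.29-fold on its brightest probe (detected on 3 of 6 arrays with the drug), with -0.17 on the other. Of the 22 NF-kB inflammatory and adhesion genes, 9 were lower and 1 higher; the mean was -0.63 ± 0.16 and the median -0.28 (camera adjusted p = 3.46e-05, adjusted p = 0.0906 with an estimated correlation). Mitotic genes were lower in 20 of 28 (26 adjusted over the list alone; mean -1.11 ± 0.28, camera adjusted p = 1.3e-26, adjusted p = 0.0584 with an estimated correlation). CCNB1 had -1.13 ± 0.21 and ASPM, a spindle protein, -1.79 ± 0.25. DNA replication genes were lower in 6 of 23 (8 adjusted over the list alone, 9 under the block; mean -0.47 ± 0.21, camera adjusted p = 6.85e-06, adjusted p = 0.289 with an estimated correlation). Endoplasmic reticulum chaperones were lower in 8 and higher in 1 of 19 (9 and 1 adjusted over the list alone; mean -0.47 ± 0.14, camera adjusted p = 7.97e-09). The adjusted p of that list was 0.0953 with an estimated correlation and 0.0209 with both it and the block. MANF, a secreted factor of the stressed endoplasmic reticulum, had -1.13 ± 0.17 and CRELD2, a protein disulfide isomerase, -1.03 ± 0.15. TGF-beta and endothelial-to-mesenchymal genes were lower in 3 of 19 (7 under the block), including THBS1, thrombospondin 1 (-0.64 ± 0.14). Their camera adjusted p was 0.00638, and the adjusted p was 0.384 with an estimated correlation and 0.038 with both it and the block. Interferon-stimulated genes were lower in 1 of 20 (10 under the block; camera adjusted p = 0.0331, adjusted p = 0.666 with an estimated correlation). Respiratory chain subunits were lower in 0 of 33 (5 under the block; mean -0.09, camera adjusted p = 0.00872, adjusted p = 0.0926 with an estimated correlation). Collagens had -0.21 on average, with 1 of 26 higher (2 higher and 9 lower under the block). Camera called them under the block alone (adjusted p = 0.219, and 0.00077 under the block).

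HIF targets did not fall as a list with propranolol at 2% oxygen: 6 of 41 were higher and 0 lower (8 higher and 3 lower over the list alone, 9 and 5 under the block; mean 0.10, camera adjusted p = 0.184). VEGFA had 0.32 ± 0.19 (adjusted p = 0.423), ADM -0.12 ± 0.16 (adjusted p = 0.799), EGLN3 -0.46 (adjusted p = 0.436), BNIP3 0.08, PDK1 0.00, HIF1A 0.12 and EPAS1 -0.02. ANGPTL4 had -1.51 ± 0.51 (adjusted p = 0.0947) and SLC2A1 -0.53 ± 0.18 (adjusted p = 0.0872), and under the block both passed as lower (adjusted p = 0.000702 and 0.0106). The other 2 probes of ANGPTL4, which the list does not count, had -1.10 and -1.16 and passed as lower without the block. VLDLR, STC2 and DDIT4 are on both the HIF and the ATF4 list. The HIF counts with the drug are therefore not separate from the rise of the ATF4 list. ANGPT2, an antagonist of the TIE2 receptor, had 1.06 ± 0.49 (adjusted p = 0.258) and passed as higher under the block (adjusted p = 3.14e-06). Glycolytic enzymes had a mean of -0.07 (2 higher and 5 lower under the block; camera adjusted p = 0.277), and the beta-adrenergic receptor and cAMP-CREB genes had 0 of 17 past the test (1 lower under the block; mean 0.03, camera adjusted p = 0.913). In all, 660 genes passed, 400 higher and 260 lower, 416 of them by at least 1.5-fold, and 2205 under the block (1124 higher, 1081 lower). BeadChips 1 and 2, 3 and 4 alone gave 0, 6 and 7 calls with 2 arrays per group, and genes called without them had the same sign on them in 98.4%, 100% and 99.1%.

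**Figure D2:**
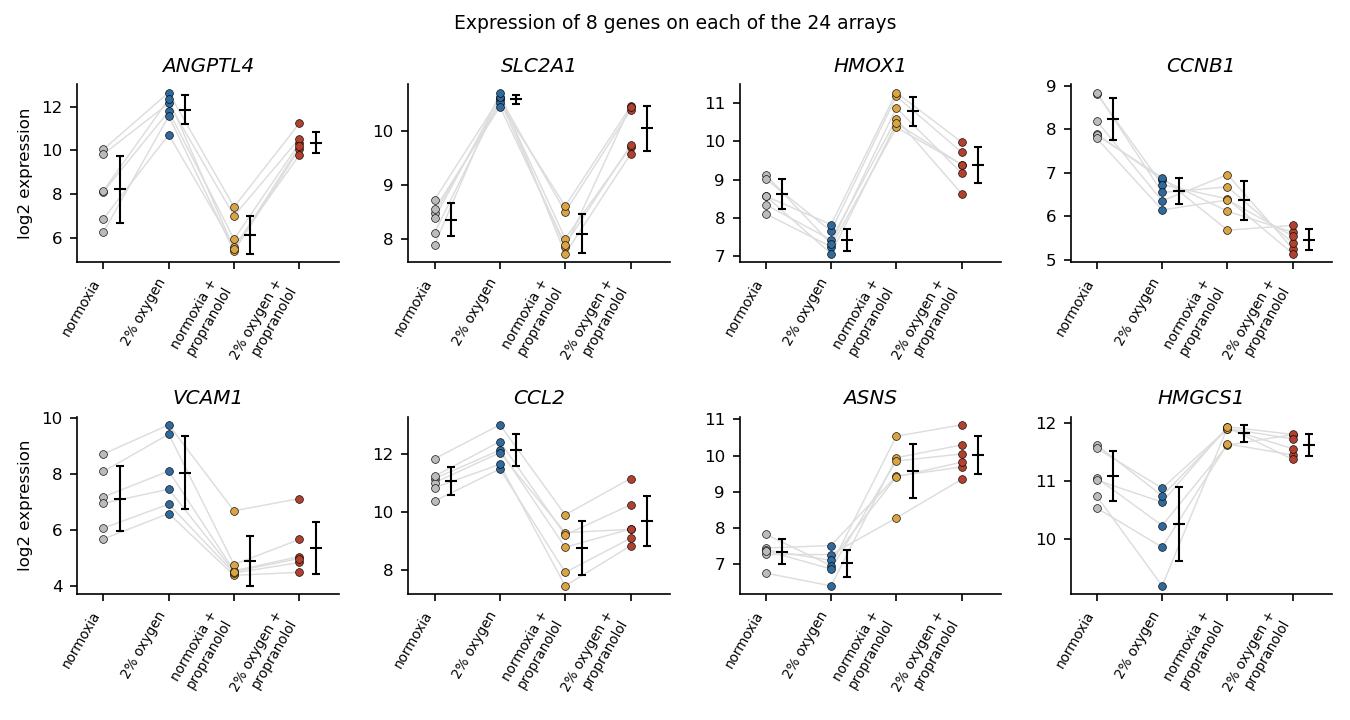
Normalized log2 expression of 8 genes on each array, with 1 point per array, grey lines joining the arrays of a set, and crosses with bars for the mean and SD of 6 arrays per group. ANGPTL4 was higher at 2% oxygen both without (3.66) and with propranolol (4.23, log2), while ASNS was higher and CCL2 lower with the drug at either oxygen level.

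The third comparison gave the drug's effect in normoxia. PSAT1 rose 4.70-fold (2.23 ± 0.29, adjusted p = 3.26e-05), ASNS 4.68-fold, SLC7A5 4.18-fold and HMOX1 4.51-fold (2.17 ± 0.21, adjusted p = 2.72e-06). Mitotic genes were lower in 28 of 28 (28 over the list alone; mean -1.61 ± 0.47, camera adjusted p = 5.15e-41, and 0.0226 with an estimated correlation). CCNB1 was 3.64-fold lower, KIF20A, a mitotic kinesin, 4.87-fold and PTTG1, securin, 3.09-fold. CCL2 had -2.32 ± 0.39 (adjusted p = 0.000384). RN7SK, the RNA that restrains the transcription elongation factor P-TEFb, rose 4.53-fold, with 2.87 on its other probe. The spliceosomal RNAs RNU4-2, RNVU1-7 and RNU1-3 rose by 2.18, 2.06 and 2.03. The ATF4 list rose in 24 of 30 (27 over the list alone; mean 1.11 ± 0.26, camera adjusted p = 7.33e-31, and 0.00746 with an estimated correlation). DDIT3 had 1.41 ± 0.17.

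DNA replication genes were lower in 17 of 23 in normoxia with the drug (20 over the list alone; mean -0.89 ± 0.37, camera adjusted p = 5.65e-18, and 0.0418 with an estimated correlation, but 0.0913 with both it and the block). CDC45 had -1.90 ± 0.32. NRF2 targets rose in 10 of 15 (10 over the list alone; mean 0.63 ± 0.08, camera adjusted p = 1.74e-10, and 0.0247 with an estimated correlation). SLC7A11, the cystine transporter, had 1.14 ± 0.20. Fatty acid synthesis genes rose in 8 of 13 (10 over the list alone; camera adjusted p = 3.66e-10, and 0.0265 with an estimated correlation). LPIN1 had 0.98 ± 0.11 and FASN, the fatty acid synthase, 0.93 ± 0.16. Cholesterol synthesis genes were higher in 7 of 20 (16 higher and 1 lower over the list alone and under the block; mean 0.52 ± 0.22, camera adjusted p = 1.24e-08, adjusted p = 0.133 with an estimated correlation). INSIG1 had 0.76 ± 0.16 and CYP51A1 0.68 ± 0.14. Autophagy genes were higher in 3 of 20 (4 over the list alone, 7 under the block; mean 0.18, camera adjusted p = 0.00329, and 0.0226 with an estimated correlation). Lysosomal genes were higher in 5 and lower in 1 of 30 (8 and 1 over the list alone, 14 and 2 under the block), with NPC1 at 1.01 ± 0.14. Camera gave an adjusted p of 7.1e-05 here, and an adjusted p of 0.255 with an estimated correlation and 0.024 with both it and the block. HIF targets were higher in 8 and lower in 1 of 41 (9 and 2 over the list alone, 15 and 5 under the block), with a mean of 0.19. The camera adjusted p was 0.00381, and the adjusted p was 0.0584 with an estimated correlation and 0.024 with both it and the block. Those that rose included BHLHE40, a transcriptional repressor of clock genes (1.12 ± 0.18), and PFKFB4, a regulator of glycolysis (0.56). ANGPTL4 was the HIF target that fell (-2.08 ± 0.51, adjusted p = 0.0109), with -0.24 and -0.21 on its other 2 probes. Endoplasmic reticulum chaperones were lower in 8 and higher in 1 of 19 (10 and 1 over the list alone; mean -0.32, camera adjusted p = 2e-04, adjusted p = 0.287 with an estimated correlation). CRELD2 had -0.93 ± 0.15, and EDEM1, which directs misfolded glycoproteins to degradation, was the member that rose (0.69 ± 0.13).

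In normoxia metallothioneins had a mean of -0.51 and 0 of 7 past the test (5 lower under the block; camera adjusted p = 0.0525, and 0.000345 under the block). Interferon-stimulated genes had a mean of -0.61 ± 0.30 in normoxia with the drug, and 2 of 20 were lower (4 over the list alone, 13 under the block; camera adjusted p = 0.000852, adjusted p = 0.423 with an estimated correlation). NF-kB inflammatory and adhesion genes were lower in 6 and higher in 2 of 22 (7 and 2 over the list alone; mean -0.43, median -0.16, camera adjusted p = 0.0424, adjusted p = 0.384 with an estimated correlation). PTGS2, cyclooxygenase 2, rose by 0.99 ± 0.19 (5 of 6 sets). Respiratory chain subunits were lower in 3 of 33 (4 over the list alone, 6 under the block), among them SDHA, a subunit of succinate dehydrogenase (-0.37 ± 0.09, and -0.14 on its other probe). Their mean was -0.13 (camera adjusted p = 0.000374, and 0.025 with an estimated correlation, but 0.117 with both it and the block). Immediate early genes were higher in 3 and lower in 1 of 15 (6 and 1 under the block; camera adjusted p = 0.0133, adjusted p = 0.131 with an estimated correlation). ATF3, a stress-induced transcription factor, had 1.09 ± 0.24 and JUN 0.65. VEGFA had 0.45 (adjusted p = 0.178), ADM 0.35 (adjusted p = 0.201) and ANGPT2 0.61 (adjusted p = 0.562, and 0.00117 under the block). In all, 971 genes passed, 473 higher and 498 lower, 563 by at least 1.5-fold, and 2657 under the block (1319 higher, 1338 lower). BeadChips 1 and 2, 3 and 4 alone gave 0, 0 and 2 calls, and genes called without them had the same sign on them in 99.3%, 100% and 98.2%. The drug's effects at the 2 oxygen levels share no array. They overlapped in 452 genes with the same sign and 0 with the opposite sign, where independent lists would give 26.8 with the same sign. Under the block 1473 had the same sign and 4 the opposite one, where independent lists would give 245.8 with the same sign. The correlation across all genes was 0.797, and genes are not independent replicates.

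**Figure D3:**
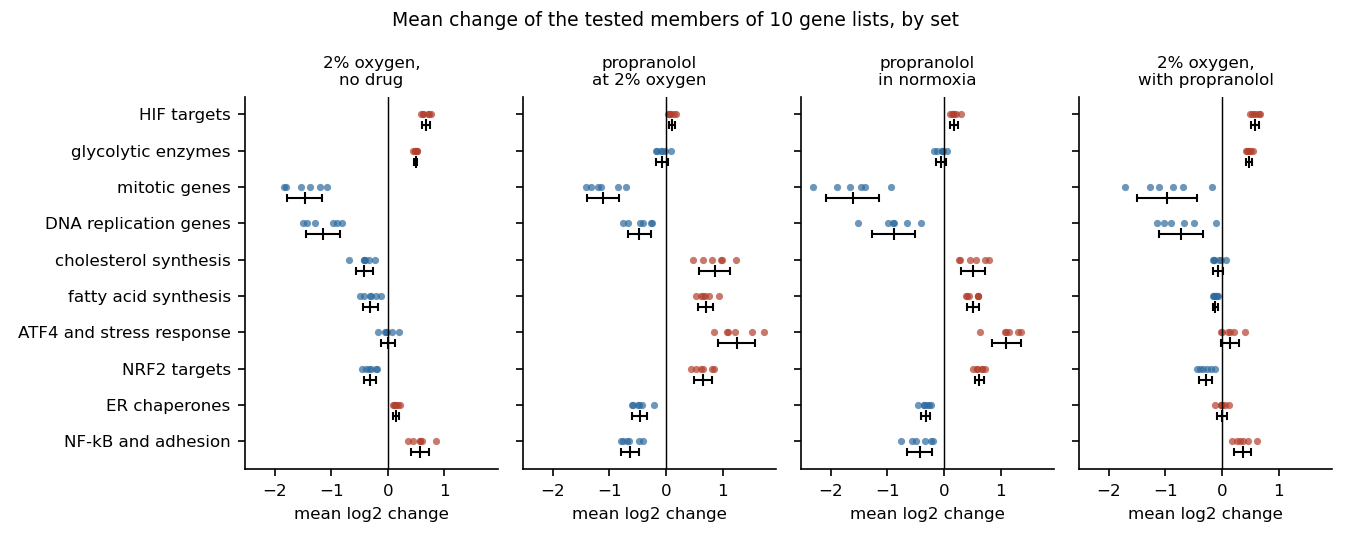
Mean log2 change of the tested members of 10 gene lists in each set (points; red above and blue below 0), with ticks and bars for the mean and SD over 6 sets, in 4 comparisons. Mitotic genes lie below 0 in 6 of 6 sets in each panel, and HIF targets lie at 0.67 without and 0.59 with propranolol in the oxygen comparisons.

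The fourth comparison gave the response to 2% oxygen in cells treated with propranolol. ANGPTL4 rose 18.8-fold (4.23 ± 0.51, adjusted p = 6.49e-05; other probes 0.87 and 1.36), ANKRD37 5.45-fold (2.45 ± 0.30), AK4 4.54-fold (2.18 ± 0.27) and SLC2A1 3.86-fold (1.95 ± 0.18, adjusted p = 9.38e-07). HIF targets were higher in 10 of 41 (20 over the list alone, 21 under the block; mean 0.59 ± 0.07, camera adjusted p = 1.43e-24, and 1.62e-06 with an estimated correlation). P4HA1 had 0.76 ± 0.09. Glycolytic enzymes were higher in 4 of 18 (10 over the list alone and under the block; mean 0.48 ± 0.05, camera adjusted p = 9.63e-14, and 0.00828 with an estimated correlation). ENO2 had 1.03 ± 0.15. ADM rose by 0.74 ± 0.16 (adjusted p = 0.0175), and did not pass without replicate 1 of the 2% oxygen group with propranolol. VEGFA had 0.72 ± 0.19 (adjusted p = 0.0815; 5 of 6 sets). EGLN3 was not detected in normoxia with the drug and was at least 1.41-fold higher (adjusted p = 0.217; 5 of 6 sets). Both passed under the block (adjusted p = 0.00817 and 0.017). HIF1A had -0.29 (adjusted p = 0.465, and 0.0218 under the block). HSD17B2 rose by 1.97 ± 0.34 (detected on 2 of 6 arrays in normoxia with the drug) and TMEM158, a membrane protein, by 1.60 ± 0.33.

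Mitotic genes were lower in 11 of 28 with 2% oxygen in the presence of the drug (26 over the list alone, 25 under the block). Their mean was -0.97 ± 0.53 (camera adjusted p = 9.13e-32, and 0.0372 with an estimated correlation, but 0.0533 with both it and the block). BIRC5 had -1.61 ± 0.27 (-0.09 on its other probe), ASPM -1.61 ± 0.25, CDK1, the mitotic kinase, -1.42 ± 0.30 and CENPF, a kinetochore protein, -1.04 ± 0.19 (detected on 2 of 6 arrays at 2% oxygen with the drug). DNA replication genes were lower in 6 of 23 (21 over the list alone, 16 under the block). Their mean was -0.72 ± 0.38 (camera adjusted p = 2.37e-21, and 0.025 with an estimated correlation, but 0.0678 with both it and the block). HMOX1 (-1.41 ± 0.21, adjusted p = 0.000502) and NQO1 (-0.77 ± 0.15) fell, the 2 of 15 NRF2 targets that passed (3 over the list alone, 4 under the block). Camera gave this list an adjusted p of 3.89e-05, and an adjusted p of 0.133 with an estimated correlation. Cholesterol synthesis genes had 0 of 20 past the test (1 lower under the block; mean -0.07 ± 0.09, camera adjusted p = 0.502) and fatty acid synthesis genes 0 of 13 (1 lower under the block; mean -0.12, camera adjusted p = 0.092). NF-kB inflammatory and adhesion genes had 0 of 22 past the test and 7 higher under the block (mean 0.37 ± 0.15, camera adjusted p = 5.99e-06, adjusted p = 0.0608 with an estimated correlation). Metallothioneins, which bind zinc and copper, had 0 of 7 past the test (3 higher over the list alone, 4 under the block) and a mean of 0.61 ± 0.06. The camera adjusted p was 0.00068, and the adjusted p was 0.287 with an estimated correlation and 0.00378 with both it and the block. Collagens were higher in 1 of 26 (2 higher and 1 lower over the list alone, 5 and 1 under the block; camera adjusted p = 0.00217, adjusted p = 0.362 with an estimated correlation, and 0.00378 with both it and the block). Immediate early genes were higher in 2 of 15, among them DUSP1 at 0.73 ± 0.15 (camera adjusted p = 0.0136, adjusted p = 0.131 with an estimated correlation). The ATF4 list (mean 0.15), heat shock proteins (-0.15), respiratory chain subunits (-0.08) and angiogenic genes (0.16) had 0 past the test. Under the block 3 of the ATF4 list were higher, 3 heat shock proteins lower and 5 angiogenic genes higher (3 over the list alone). Camera called them at adjusted p = 0.0196, 0.00848, 0.00217 and 0.0484, and the adjusted p was 0.612, 0.376, 0.05 and 0.133 with an estimated correlation. TGF-beta genes were called under the block alone (mean 0.21; 1 of 19 higher, and 7 higher and 2 lower under the block). Their camera adjusted p was 0.1, 0.0099 under the block and 0.117 with both it and an estimated correlation.

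In the presence of propranolol, 122 genes passed the test with 2% oxygen, 76 higher and 46 lower, and 915 under the block (528 higher, 387 lower). BeadChips 1 and 2, 3 and 4 alone gave 0 calls each, and the 12, 23 and 44 genes called without them had the same sign on them in 100%. Of the 552 genes called without the drug, 96 were also called with it in the same direction and 0 in the opposite one, where independent lists would give 2.61 (correlation across all genes 0.738). Under the block 662 of 2010 were called in both in the same direction and 2 in the opposite one. There independent lists would give 76.8 in the same direction.

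**Figure D4:**
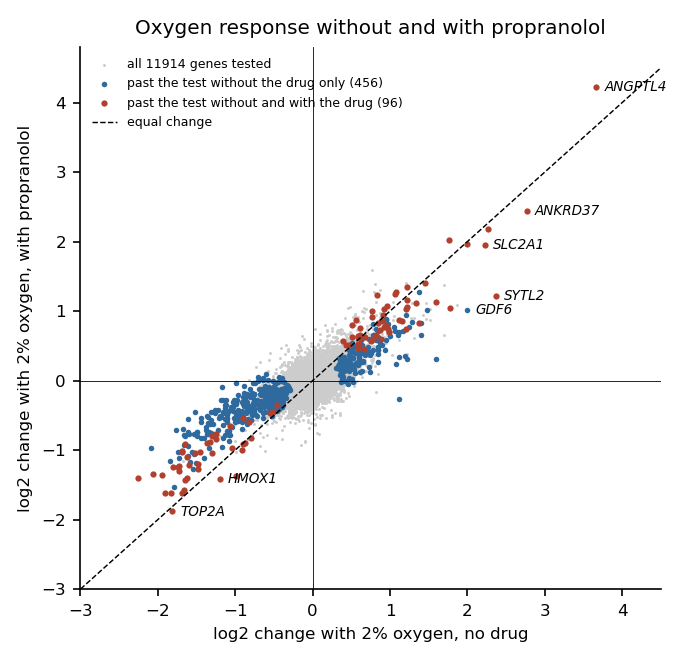
Log2 change with 2% oxygen without propranolol (horizontal axis) against the change with it (vertical axis) for all 11914 genes tested, each a difference of the means of 6 arrays per group; the dashed line marks equal change. Of the genes past the test without the drug, 96 passed in both (red) and 456 did not pass with the drug (blue).

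Whether propranolol changed the oxygen response itself was tested by the interaction. In limma 0 genes passed, both without the block (316 genes at an unadjusted p under 0.05, smallest adjusted p = 0.37) and with it (957 genes, smallest adjusted p = 0.0559). The preset genes had an adjusted p of 1 without the block; ANGPTL4 had a difference of 0.57 ± 0.73 (-0.86 and -0.95 on its other 2 probes), HMGCS1 0.63 ± 0.31, ADM -0.47 ± 0.22, EGLN3 -0.44 (not detected in either normoxia group), SLC2A1 -0.28 and VEGFA -0.13. Camera called 8 lists, none of which held with an estimated correlation. Mitotic genes had a mean difference of 0.50 ± 0.32 (camera adjusted p = 4.18e-13, adjusted p = 0.207 with an estimated correlation), DNA replication genes 0.42 ± 0.27 (3.55e-12, adjusted p = 0.0953 with an estimated correlation) and cholesterol synthesis genes 0.35 ± 0.14 (5.58e-09, adjusted p = 0.131 with an estimated correlation). Each of these was above 0 in 6 of 6 sets, with an exact two-sided sign-flip p of 0.0312, the smallest that 6 sets allow. That p counts the 2 sets that share a code as independent. HIF targets had -0.08 ± 0.05, below 0 in 6 of 6 sets (camera adjusted p = 0.0432, adjusted p = 0.173 with an estimated correlation), and glycolytic enzymes -0.01 (camera adjusted p = 0.861). Under the block camera also called TGF-beta genes (adjusted p = 0.00133), collagens (0.0301), interferon-stimulated genes (0.00273) and metallothioneins (0.00366), and none of these held with an estimated correlation.

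On genes called for their oxygen response in other sets, the response with propranolol was 0.626 ± 0.173 of that without it (SD over 6 sets, range 0.354 to 0.884). It was smaller in 6 of 6 sets (exact two-sided sign-flip p = 0.0312), and the mean signed change went from 0.97 to 0.63 log2 units. Genes that rose with 2% oxygen retained 0.786 ± 0.095 and genes that fell 0.554 ± 0.225. The share depended on how genes were chosen, with choices made after seeing the data: 0.716 ± 0.158 on genes called by the mean of both oxygen responses (6 of 6 sets smaller) and 0.924 ± 0.219 on genes called with propranolol (4 of 6 sets smaller, exact p = 0.469). On the latter, genes that rose retained 1.02 ± 0.121 and genes that fell 1.02 ± 0.727.

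The title of the series speaks of reversal, which was counted as genes called with 2% oxygen and called the opposite way with propranolol at 2% oxygen. Of the 552 oxygen-responsive genes, 62 were moved back (35 that rose and then fell, 27 that fell and then rose), and 63 were moved further the same way, 58 of them downward. Under the block 529 of 2010 were moved back and 229 further. Independent lists would give 16.3 and 14.3 genes (186 and 186 under the block), and simulated unchanged groups that share the 2% oxygen arrays gave 0, a count fixed by their median of 0 calls in either comparison. Those arrays were then split between the comparisons, 3 and 3 over 20 splits. The median was 21 genes moved back (14 to 27) and 23 further, and 186 and 103.5 under the block. Without the block, differences between the split sets enter both comparisons with the same sign and favour genes moved further. The block removes these differences. The correlation of the changes was -0.143 where simulated unchanged groups gave -0.462, and the covariance -0.0133 against -0.0161. The simulation redrew arrays without regard to sets, so it lost their pairing. It therefore cannot say how much opposition the shared arrays alone would give here. With the arrays split, the correlation and covariance were 0.052 and 0.0066 on average (-0.034 and -0.0028 under the block).

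Genes that fell with 2% oxygen and rose with propranolol at 2% oxygen included HMOX1 (-1.20, then 1.96), NQO1 (-1.24, then 1.02), MYCN (-1.73, then 2.59), ELOVL6 (-1.16, then 0.66), ACAT2 (-0.97, then 1.12) and NID2, a basement membrane protein (-0.80, then 0.81). Those that rose and then fell included SELE (1.08, then -2.40), TNFAIP3 (0.85, then -0.60), CD69, a lymphocyte activation antigen (1.60, then -1.91; detected on 3 of 6 normoxia arrays and only 1 of 6 at 2% oxygen with the drug), GDF6, a bone morphogenetic protein (1.99, then -1.66; detected on 4 of 6 arrays in each of these groups), and SYTL2 (2.36, then -1.17). Propranolol moved many of these genes the same way in normoxia. Under the block, HMOX1 (2.17), MYCN (1.89), NQO1 (0.55), NID2 (0.57), SELE (-1.56), CD69 (-0.63) and GDF6 (-0.68) passed there. ELOVL6 (0.14), ACAT2 (0.44), TNFAIP3 (-0.20) and SYTL2 (-0.02) did not. Moved back therefore does not by itself mean that the drug acted on the oxygen response. By list, 3 of 3 oxygen-called cholesterol synthesis genes were moved back (11 of 11 under the block), 2 of 2 NRF2 targets (5 of 6) and 4 of 5 NF-kB inflammatory and adhesion genes (9 of 13). Of the 16 oxygen-called HIF targets 0 were moved back and 3 further (4 and 7 of 25 under the block), and of the 27 oxygen-called mitotic genes 0 were moved back and 20 further (0 and 26 of 28). These counts use the brightest probe of each gene. The other 2 probes of ANGPTL4, a HIF target, passed as higher with 2% oxygen (1.73 and 2.30) and as lower with propranolol there (-1.10 and -1.16). As given above, the other probe of SYTL2 hardly moved with 2% oxygen. With the drug there, that of SELE hardly moved and that of MYCN rose less than its brightest probe. The counts by list were not tested against each other.

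With an estimated correlation, camera calls held for 6 lists with 2% oxygen, 4 with propranolol at 2% oxygen, 7 with propranolol in normoxia and 4 with 2% oxygen in the presence of the drug. Lists that camera did not call in any comparison without the block included endothelial identity genes (1 of 27 higher with 2% oxygen, 4 higher and 6 lower under the block, and 0 past the test with the drug at 2% oxygen, 3 higher and 4 lower under the block; adjusted p = 0.334 and 0.807). The others were p53 targets (0.276 and 0.908), apoptosis regulators (0.929 and 0.198), cytosolic ribosomal proteins (0.711 and 0.209) and the beta-adrenergic list (3 of 17 higher with 2% oxygen, adjusted p = 0.137). Angiogenic genes had 0 higher and 2 lower of 28 with the drug at 2% oxygen (8 and 6 under the block; camera adjusted p = 0.885). Markers of other cells were not called for smooth muscle and pericytes (adjusted p = 0.978 with 2% oxygen, 0.247 with the drug at 2% oxygen and 0.146 in normoxia, there 0.043 under the block and 0.0996 with both it and an estimated correlation), fibroblasts (0.984 and 0.898) or leukocytes (0.864 and 0.772). With the drug at 2% oxygen the mean was -0.47 ± 0.08 for the 5 smooth muscle and pericyte markers (median -0.11). It was -0.22 for the 8 fibroblast markers (median -0.13). Both means were below 0 in 6 of 6 sets (2 lower in each list under the block). They lay in the direction of the TGF-beta and collagen lists there. TAGLN, which had -1.77, belongs to both the smooth muscle and the TGF-beta list. With 2% oxygen the means were also in the direction of those lists. Smooth muscle and pericyte markers had 0.24 (median -0.01, above 0 in 6 of 6 sets) and fibroblast markers 0.18 (median 0.08, 5 of 6 sets). Epithelial and amnion markers had 0 of 7 past the test (2 higher under the block with 2% oxygen, and 3 with it in the presence of the drug, where 2 passed over the list alone). Their mean was 0.37 with 2% oxygen (camera adjusted p = 0.158, 0.0247 under the block and 0.0684 with both it and an estimated correlation) and 0.41 with 2% oxygen in the presence of the drug (camera adjusted p = 0.0113, adjusted p = 0.05 with an estimated correlation, and 0.0235 with both it and the block). The medians of the epithelial and amnion markers were 0.09 with 2% oxygen and 0.19 with it in the presence of the drug. The single erythroid gene tested, HBA2, and the 3 lymphatic genes, PROX1, RELN and LYVE1, did not pass in any comparison without the block. Under the block, LYVE1, a hyaluronan receptor, passed as lower with 2% oxygen (-1.68 ± 0.13, adjusted p = 4.77e-08) and as higher with the drug at 2% oxygen (1.29 ± 0.13, adjusted p = 6.68e-07).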

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

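The tests of the retained share on genes called by the mean of both oxygen responses and without the mitotic and DNA replication lists were chosen only after the result was seen. Arrays and sets were compared in 219 groups of 6, and in 11 of them 1 value stood far from the other 5, where chance gives about 10.95. By set, 5 of the 10 values that belong to a set were in set 1, 2 in set 4, 1 in set 5 and 2 in set 6. Replicate 2 of the normoxia group with propranolol had 20738 detected probes, against 18860 to 19529 on the other 5 arrays. With 2% oxygen, ADM had 0.17 in set 5 (1.20 to 1.65 in the others), P4HA1 0.62 in set 4 (0.94 to 1.05), and immediate early genes 0.49 in set 1 (0.15 to 0.28). With propranolol at 2% oxygen, TRIB3 had 1.59 in set 1 (2.25 to 2.63), NPC1 1.73 in set 6 (1.11 to 1.33), ASPM -0.91 in set 1 (-2.13 to -1.73) and SELE -2.88 in set 4 (-2.41 to -2.14). PTGS2 had 0.00 in set 1 with propranolol in normoxia (0.98 to 1.45 in the others), and SLC2A1 2.61 in set 1 with 2% oxygen in the presence of the drug (1.69 to 1.88). The difference of NF-kB inflammatory and adhesion genes between the oxygen responses was 0.09 in set 6 (-0.34 to -0.21).

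Among probes that carry no gene symbol, 5205 were tested apart from the named genes. Of these, 51 passed with 2% oxygen (19 higher, 32 lower), 81 with propranolol at 2% oxygen (52 higher, 29 lower), 105 with propranolol in normoxia (49 higher, 56 lower) and 5 with 2% oxygen in the presence of the drug (4 higher, 1 lower). Under the block 231, 286, 358 and 93 passed, in the same order. What these probes measure was not analysed here.

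For 8 lists the oxygen response with the drug differed from that without it by camera at its preset correlation. The mean differences were 0.50 for mitotic genes, 0.42 for DNA replication genes, 0.35 for cholesterol synthesis genes, 0.19 for fatty acid synthesis genes, 0.15 for the ATF4 list, -0.20 for NF-kB inflammatory and adhesion genes, -0.14 for endoplasmic reticulum chaperones and -0.084 for HIF targets. With the correlation estimated from the data, 0 of the 8 passed.

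The first pattern is in the 51 mitotic and DNA replication genes, which had -1.32 ± 0.29 (SD over 6 sets) with 2% oxygen alone, -1.28 ± 0.42 with propranolol alone and -2.14 ± 0.29 with both, where the separate changes add up to -2.61 ± 0.39. The shortfall of 0.47 ± 0.28 was above 0 in 6 of 6 sets (0.10 to 0.88; exact two-sided sign-flip p = 0.0312, the smallest possible). A floor of the signal would spare brighter genes, and the 25 brighter genes still had a shortfall of 0.41, above 0 in 6 of 6 sets. The 26 dimmer ones had 0.52, so a part played by a floor is left open. The normalization as a cause was argued against by 0.954 of the shortfall being kept on median-scaled values. On the authors' values 0.959 was kept, but these columns share 1 median, as quantile normalization leaves them, and so are no independent check. A candidate explanation that was not tested is that the 2 exposures act in part on the same dividing cells; it is a hypothesis from the same data, these arrays hold no measure of division, and counts of cells that take up a DNA label in the 4 groups would test it.

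The smaller oxygen response with propranolol, a retained share of 0.626, is the second pattern. A floor of the signal as the whole cause was argued against by the brighter of the chosen genes, which retained 0.707 ± 0.152. The dimmer ones retained 0.560 ± 0.197, a difference in the direction that a floor would give, so a part played by it is left open. The share was 0.627 without the mitotic and DNA replication lists, but these hold 47 of the 362 genes that fell, so cell division genes as the cause cannot be told apart. Choosing genes on the untreated response was not the whole of it, since genes called by the mean of both responses retained 0.716 ± 0.158; genes called with propranolol retained 0.924 ± 0.219, so part of the size of the share rests on that choice. A smaller response in treated cells may remain; genes that fell retained 0.604 ± 0.214 and genes that rose 0.889 ± 0.107 on genes called by the mean response, but 1.02 ± 0.727 and 1.02 ± 0.121 on genes called with propranolol, and no biological cause was tested.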

How the results depend on the processing

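The choices of genes for the retained share named in this part were made only after the result was seen. Of 7850 values of named genes under the alternatives, 7220 stayed on the same side of the threshold, 593 were no longer past it, 37 came to pass it and 0 reversed. The largest changes were named for the same sign in 6 of 6 sets, so they could hardly reverse on fewer arrays. A gene not called counted as reversed only if it came to be called the opposite way. The 0 reversals are therefore weak evidence on direction. Of 750 list tests 659 stayed, 69 were lost and 22 gained, 43 of the losses with an estimated correlation. Counts are given here for 2% oxygen, propranolol at 2% oxygen, propranolol in normoxia, 2% oxygen with the drug, and genes moved back, in that order. Blocks removed the spread between sets and raised the counts: the set as replicate block gave 2010, 2205, 2657, 915 and 529, the description code as replicate block 1768, 1968, 2373, 762 and 449, and the code as random block 1473, 1688, 2131, 560 and 303, with 1 interaction gene. The BeadChip as block gave 888, 1021, 1473, 206 and 142. With 2 arrays per group, BeadChips 1 and 2 gave 0, 0, 0, 0 and 0, BeadChip 3 gave 1, 6, 0, 0 and 0, and BeadChip 4 gave 0, 7, 2, 0 and 0; fewer arrays lowered these counts by construction. The retained share was not run within BeadChips, where leaving a set out leaves 1 array per group. A threshold of 1.5-fold left 367, 416 and 563 genes in the first 3 comparisons and 40 moved back. Array weights gave 251 genes for 2% oxygen with the drug and averaging the arrays of the shared code gave 57, and fitting only the groups compared gave 37 genes moved back; the cause was not tested. The retained share was 0.924 on genes called with propranolol, 0.876 on genes called in both responses, 0.716 on genes called by the mean response and 0.627 without the mitotic and DNA replication lists.

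Leaving out 1 array or set gave 286 to 583 genes with 2% oxygen, 379 to 681 with propranolol at 2% oxygen, 579 to 1033 with propranolol in normoxia, 39 to 174 with 2% oxygen in the presence of the drug, 0 to 1 for the interaction, 20 to 72 moved back and a retained share of 0.568 to 0.698. Counts moved by over 1.5 times without these sets: 4 and 5 with 2% oxygen (286 and 330), 2, 4 and 5 with propranolol at 2% oxygen (431, 379 and 422), and 3, 4 and 5 with propranolol in normoxia (621, 638 and 579). With 2% oxygen in the presence of the drug they were sets 1, 4 and 5 (41, 39 and 55), replicate 1 of the treated 2% oxygen group (76) and replicates 4 and 5 of the treated normoxia group (69 and 74), and for genes moved back sets 1, 4 and 5 (38, 20 and 35). The interaction had 1 gene without normoxia replicate 6. Signal over background limits what could be tested: CA9 and ADRB1 were not among the genes tested, and the change of EGLN3 is a lower bound.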

Other observations

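Every test of the small RNAs in this part was of a pattern noticed in the data, the swaps within sets for lists were chosen only after the result was seen, and genes named in the next 2 paragraphs were chosen after their values were seen. Small structural RNAs of the nucleus and cytoplasm were higher with propranolol: of 17 tested (11 spliceosomal RNAs, 7SK, 7SL and 4 Y RNAs), 9 rose at 2% oxygen and 13 in normoxia, and 0 fell. Their mean changes were 0.83 ± 0.46 and 1.29 ± 0.48 (SD over 6 sets, above 0 in 6 of 6 sets, exact two-sided sign-flip p = 0.0312, the smallest possible). RNY1, which binds the Ro protein, rose by 1.63 and 1.98 log2 units, RNY4 by 1.34 and 1.88, and VTRNA1-1, a vault RNA detected on 4 of 6 arrays of each group without the drug, by 1.12 and 1.48. RN7SL1, the RNA of the signal recognition particle, had -0.08 and -0.03, and RNY3 had 0.10 and -0.04. Genes of the same family, such as RNU1-1 and RNU1-3 or RNU4-1 and RNU4-2, were counted separately. Of 133 small nucleolar RNAs 1 and 6 rose and 0 fell (4 higher and 6 lower, and 11 and 6, under the block), with means of -0.01 and 0.06. Among those that rose in normoxia, SNORD3A had 1.42, SNORD3D 1.37 and SNORD46 1.27 (detected on 4 of 6 normoxia arrays). With 2% oxygen alone 0 of the 17 passed in limma, with or without the block (mean -0.03 ± 0.19), and with 2% oxygen in the presence of the drug 0 passed and 5 were lower under the block (mean -0.50 ± 0.32, below 0 in 6 of 6 sets).

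Of the further genes named next, KLF4 and HSPA5 passed without the block and the others under the block alone. KLF4, a flow-responsive transcription factor of endothelium, rose by 1.66 ± 0.38 with propranolol at 2% oxygen and by 1.65 ± 0.38 in normoxia. HSPA5, the endoplasmic reticulum chaperone BiP, fell by 1.15 ± 0.22 and 0.72 ± 0.22. The metallothioneins MT1E and MT1G had -1.10 and -0.69 with propranolol in normoxia and 1.04 and 1.03 with 2% oxygen in the presence of the drug, and passed under the block alone. So did the interferon-induced genes MX1 and IFIT1 with propranolol in normoxia (-1.68 and -1.57; IFIT1 was detected there on 5 of 6 arrays). TAGLN, an actin-binding protein of contractile cells, had 1.22 ± 1.05 with 2% oxygen (adjusted p = 0.659, and 6.67e-05 under the block) and -1.77 with propranolol at 2% oxygen (adjusted p = 0.42, and 6.69e-07 under the block).

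The rise of small structural RNAs is the third pattern weighed: capture of all short RNAs would raise small nucleolar RNAs alike, but their mean change was 0.024 of that of the spliceosomal RNAs, and 0.057 in the brightest 34 of 133. Against spliceosomal RNAs as bright, the share was 0.152 in the 13 with a mean level of at least 7. It was 0.461 in the 4 with at least 8, mostly from SNORD3A (0.84 at 2% oxygen, 1.42 in normoxia) and SNORD3D (0.81 and 1.37). SNORD13 had 0.07 and 0.57, and SNORA12 -0.08 and 0.31. A change in the capture or labelling of some short RNAs is therefore left open. Brighter or dimmer arrays were argued against by a correlation of 0.067 between the rise and the difference in median signal over 12 pairs of arrays (permutation p = 0.837), though it was 0.312 without the 2 pairs farthest from the median. The normalization was argued against by 0.991 of the rise being kept on median-scaled values. The authors' values kept 0.96, but their columns share 1 median, as quantile normalization leaves them, so they are no independent check of it. A candidate explanation that was not tested is a change in the level or 3' processing of these RNAs with the drug. It is a hypothesis from the same data, and these arrays cannot separate it from a change in how these RNAs are labelled.

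Other groupings of the arrays were tried for each count. For the number of genes in 4 comparisons, chance could be excluded: of 100 splits, 1, the real one, called as many. With 2% oxygen the real split gave 552 and the highest other 291, with propranolol at 2% oxygen 660 and 104, with propranolol in normoxia 971 and 144, and with 2% oxygen in the presence of the drug 122 and 30. For genes moved back (62, highest other 0; 1 split) chance cannot be told apart this way, since the other splits called a median of 0 genes in either comparison. For the interaction it cannot be told apart either, since any split gives at least its 0 genes (100 of 100, highest 7). Among the 32 swaps within sets, under the block, 1 was as large in each comparison: 2010 against 316, 2205 against 271, 2657 against 824 and 915 against 40. The swaps count sets 1 and 5, which share a code, as independent. The next counts of lists adjust camera within 1 comparison and so can differ from the lists called over all comparisons. For the number of lists called at the preset correlation, chance could not be excluded with 2% oxygen (15, highest other 17; 5 splits) or for the interaction (7, highest other 16; 53 splits). By random splits it could be excluded with propranolol at 2% oxygen (14 and 14; 3 splits), in normoxia (15 and 17; 3 splits) and with 2% oxygen in the presence of the drug (14 and 14; 2 splits). By the 32 swaps within sets it could be excluded only for the last (15, highest other 14; 1 swap). It could not be excluded there with 2% oxygen (17 and 17; 3 swaps), with propranolol at 2% oxygen (15 and 15; 4 swaps) or in normoxia (17 and 17; 2 swaps). Since random splits called 6 to 8 lists at their median, a camera call at the preset correlation carries less weight here than a call that holds with an estimated correlation.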
